A study of Mus musculus with 6 samples.

How the data were processed

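Total RNA of mouse B16F10 melanoma cells was made into BGISEQ-500 libraries, 3 from cells given vehicle (0.05% DMSO) and 3 from cells given SAS for 24 h, per the labels' protocols. The authors deposited 1 table of values that the file headers name FPKM (by definition, fragments scaled to transcript length and to the mapped fragments of the library). Values were given to 2 decimals, with 1 column per library. FastQC, HISAT and Bowtie2 are named without versions or roles, per the submitters' processing notes. The program that computed FPKM, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. By that definition a value is a share, and a rise of abundant genes lowers the rest.

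Each column was matched to a library by its name. Columns named 24 h were taken as SAS, the group whose own treatment label gives 24 h, and columns named 0 h as vehicle, the remaining group, with the last number as the replicate number. This match rests on elimination, and the meaning of 0 h is not stated. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

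Rows carry NCBI Gene identifiers, of which 16206 of 16315 (99.3%) matched a symbol in the mouse RefSeq table of assembly GRCm38.p6, used for names alone. In all 6 libraries, 377 genes were listed at 0. Depth in fragments is unknown: of 39 genes with low values, 13 moved in whole steps within a tolerance of 0.15, and values with 2 decimals are too coarse to recover reads. No count test was run, and no interval from counting was computed. No library pair looked like 1 library deposited under both names: at most 0.85% of genes had identical values in any pair.

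The test used limma 3.58.1 in R 4.3.3 with an intensity trend on log2(FPKM + 1), over 10615 genes with a mean of at least 0.5 FPKM, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. On data simulated for this comparison over the 10615 genes with 200 changed genes in each of 20 runs, the test recovered 28.8% of genes changed 1.2-fold, 89.6% of those changed 1.5-fold and 99.2% of those changed 2-fold, and 4% of calls were false. The simulation drew independent noise and planted far fewer changed genes than the 3969 called in the data. It planted changes only in genes above about 1 FPKM in vehicle, so lower genes such as Slc7a11 were not covered. Its rates therefore need not hold for the data themselves. Genes with near-identical copies, such as ferritin, histone, ribosomal protein and glutathione S-transferase genes, may share reads, and how the authors assigned these is not given in the sources used here.

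The 45 gene lists were fixed before the data were examined, as were the tests and the alternatives not named below as added. Lists with at least 3 tested members were tested with camera (preset inter-gene correlation 0.01), adjusted over the 43 lists tested. Camera compares a list with the other genes, and a list's count is also given adjusted over the list alone. The text names Slc7a11, Slc3a2, Cd274, Irf4 and Egr1 in any case. It also names the 10 highest and the 10 lowest log2 fold changes among changed genes with separated groups and a mean of at least 5 FPKM in the higher group, unnamed gene models left out. In each list it names up to 4 changed members with the largest absolute log2 fold change. Some genes that this rule takes are not reported here. Other genes were chosen after their values were seen: those in the opening of the closing observations and the leukocyte genes discussed there.

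The alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 FPKM, size factors, libraries rescaled to a common sum, quantile normalization, a replicate block, limma without the trend, with robust estimation or with array weights, each library left out in turn, an estimated inter-gene correlation, and fry, which tests whether a list's genes move on balance one way. With an estimated correlation, camera also rests on the few residual degrees of freedom of the 6 libraries. A call lost in that setting therefore need not mean that the members are correlated. A correction for GC content and transcript length, from GENCODE M21 transcripts (1 per gene, 98% of tested genes), and lists without NRF2 list members were added after the data were seen. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.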

Results

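Messenger RNA was profiled in B16F10, a pigmented melanoma cell line derived from a C57BL/6 mouse. The series concerns inhibition of xCT, the cystine-importing chain of the plasma membrane transporter system xc-. Cells received SAS, a compound the labels name only by these letters, at a labelled concentration of 500 (unit written as μm) for 24 h, or 0.05% DMSO as vehicle. Each group held 3 libraries sequenced on the BGISEQ-500 platform. The deposited values are FPKM for 16315 genes, and the fragments behind them are unknown, so the FPKM sums of 590238 to 617275 per library do not measure depth. Between 9746 and 9826 genes reached 1 FPKM in a library, and the 10 most abundant genes took 10.9 to 12.35% of the sum. Pearson correlations of log2(FPKM + 1) across genes, which are not independent replicates, were 0.9973 to 0.9983 within vehicle, 0.9968 to 0.9978 within SAS and 0.9885 to 0.9919 between the groups. The first principal component carried 70.6% of the variance and placed the 3 SAS libraries apart from the 3 vehicle libraries.

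The comparison of SAS with vehicle asks how the transcriptome of melanoma cells differs after a day with the compound. SAS-treated cells held more mRNA of most NRF2 targets tested, among them Hmox1 and Nqo1, of the inhibitor-of-differentiation genes Id1 and Id3 and of most pigment cell genes tested. They held less mRNA of most DNA replication and mitosis genes tested and of many genes of the ATF4-driven amino acid response. With inter-gene correlation estimated from the libraries, which also leaves camera few degrees of freedom, the NRF2 list passed. The pigment cell (camera adjusted p = 0.26), replication (adjusted p = 0.26), mitosis (adjusted p = 0.273) and ATF4 lists (adjusted p = 0.322) did not. Of 10615 genes tested with limma, 3969 (37.4%) changed at a Benjamini-Hochberg adjusted p below 0.05, with 2006 higher and 1963 lower in SAS. Most shifts were small: the median absolute log2 fold change of the changed genes was 0.312, or 1.24-fold, and 50 genes changed at least 2-fold, 43 upward and 7 downward. That count rose to 136 with a pseudocount of 0.1 in place of 1. The table's columns name the vehicle libraries 0 h and the SAS libraries 24 h, whereas the protocol describes 24 h of incubation for both. If 0 h means cells collected before incubation, every difference given here also contains a day of culture.

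Among genes at or above 5 FPKM in the higher group and fully separated between groups, the increases with the highest log2 fold changes were those of Id1, Hmox1 and Serpinf1. Id1 (NCBI Gene 15901), a repressor of basic helix-loop-helix transcription factors, rose from 6.2 ± 0.982 to 28.4 ± 7.78 FPKM (SD, n = 3 per group, as for all means here; log2 fold change 2.01, SE 0.15, limma adjusted p = 6.78e-06). Hmox1 (NCBI Gene 15368), the inducible heme oxygenase, rose from 61.1 ± 4.34 to 241 ± 6.09 FPKM (log2 fold change 1.96, SE 0.06, limma adjusted p = 1.96e-08). Serpinf1, which encodes the secreted factor PEDF, rose from 20.2 ± 1.71 to 75.7 ± 6.58 FPKM. Phyhd1 stood at 1.08 FPKM in each vehicle library and rose to 6.15 ± 0.675 FPKM. Nr4a3, an orphan nuclear receptor, rose from 2.38 ± 0.358 to 10.3 ± 0.609 FPKM, and Id3 from 34.7 ± 5.9 to 115 ± 29.5 FPKM. Slc24a4, a sodium, potassium and calcium exchanger, rose from 1.14 ± 0.346 to 5.49 ± 0.90 FPKM. Biliverdin reductase B (Blvrb) rose from 44.2 ± 2.83 to 134 ± 11.3 FPKM, the proline synthesis enzyme Pycr1 from 2.5 ± 0.188 to 9.12 ± 0.668 FPKM and the quinone reductase Nqo1 from 3.25 ± 0.25 to 11.03 ± 0.586 FPKM.

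The retinoic acid hydroxylase Cyp26b1 fell from 6.5 ± 0.628 to 1.85 ± 0.236 FPKM (log2 fold change -1.40, SE 0.09, limma adjusted p = 1.62e-06). The kinase gene Prkcq fell from 25.1 ± 2.57 to 8.91 ± 0.772 FPKM, the transcriptional cofactor Vgll3 from 30.5 ± 2.68 to 11.3 ± 1.3 FPKM and the nuclear receptor Nr2f2 from 14.8 ± 1.48 to 6.51 ± 1.03 FPKM. Slc1a4, a neutral amino acid transporter, fell from 10.6 ± 1.09 to 4.25 ± 0.88 FPKM. The imprinted gene Mest fell from 37.05 ± 1.6 to 17.1 ± 0.235 FPKM, the xylosyltransferase Gxylt2 from 50.3 ± 3.32 to 24.1 ± 2.74 FPKM and the chemokine Cxcl1 from 7.67 ± 0.326 to 3.43 ± 0.436 FPKM. The pseudokinase Trib3 fell from 40.6 ± 3.14 to 20.5 ± 0.767 FPKM, and Aldh18a1, which makes the precursor of proline and ornithine, from 47.9 ± 1.43 to 24.4 ± 1.48 FPKM.

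**Figure D1:**
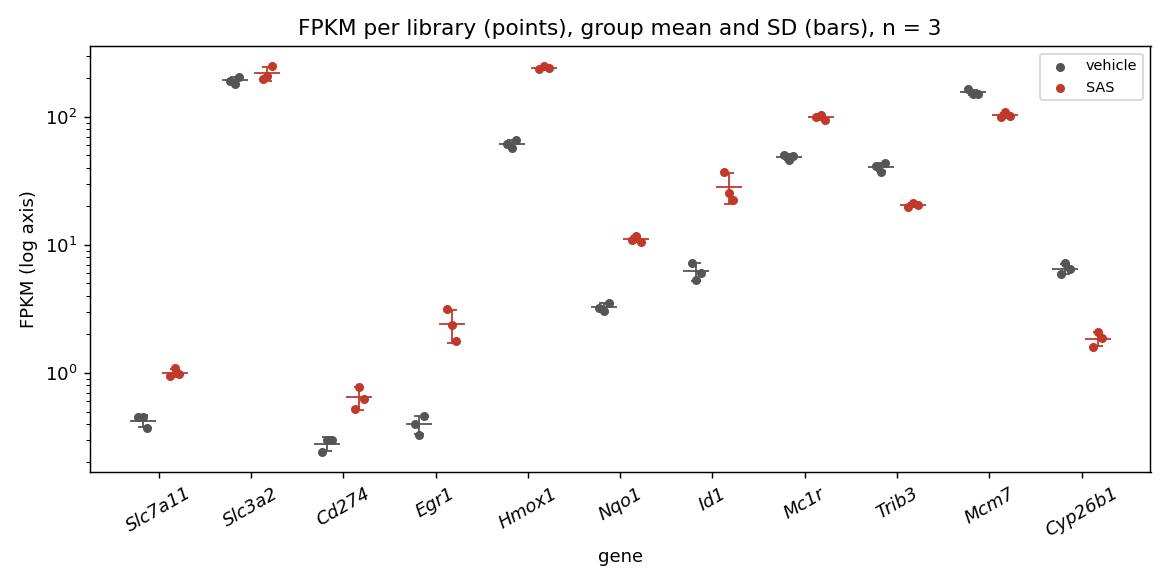
FPKM (log axis) of 11 named genes in each of the 3 vehicle (grey) and 3 SAS (red) libraries, with horizontal bars at group means and vertical bars of 1 SD. The SAS points lie above the vehicle points for Slc7a11, Cd274, Egr1, Hmox1, Nqo1, Id1 and Mc1r and below them for Trib3, Mcm7 and Cyp26b1, while the Slc3a2 points overlap.

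Slc7a11 (NCBI Gene 26570), which encodes xCT itself, was expressed at a low level and rose from 0.423 ± 0.0462 to 1.01 ± 0.0737 FPKM (log2 fold change 0.50, SE 0.06, limma adjusted p = 0.000181). Its partner chain Slc3a2 (NCBI Gene 17254) was abundant, at 192 ± 12.3 FPKM in vehicle and 219 ± 27.5 FPKM in SAS, and did not pass the test (adjusted p = 0.101); it passed with a replicate block (adjusted p = 0.0351), with array weights (adjusted p = 0.025) and without SAS replicate 1 (adjusted p = 0.0322). In the list of cystine and cysteine transport, 2 of 6 tested members rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.797). The members that rose were Slc7a11 and the lysosomal cystine exporter Ctns, from 14.9 ± 1.4 to 20.4 ± 2.7 FPKM. Slc1a4 and Slc7a5 fell. The call of Slc7a5 was lost without Vehicle replicate 1, 2 or 3 (adjusted p = 0.058, 0.104 and 0.112) and without SAS replicate 1 or 2 (adjusted p = 0.12 and 0.0935).

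Most tested targets of NRF2, the transcription factor of the response to oxidants and electrophiles, rose. In this list, 22 of 29 tested members rose and 0 fell (22 and 0 adjusted over the list alone, camera adjusted p = 8.26e-14, and adjusted p = 0.0462 with an estimated correlation). Their median log2 fold change was 0.604. Besides Hmox1, Blvrb and Nqo1, the glutathione synthesis subunit Gclm rose from 18.2 ± 0.864 to 46.5 ± 1.19 FPKM. Of the list of glutathione synthesis and recycling, 7 of 16 tested members rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.0104, and adjusted p = 0.322 with an estimated correlation). The transpeptidase Ggt1 rose from 2.05 ± 0.242 to 6.49 ± 0.395 FPKM and the microsomal transferase Mgst1 from 11.4 ± 1.5 to 26.4 ± 3.4 FPKM, while Chac1, which degrades glutathione, fell from 61.6 ± 6.46 to 31.5 ± 0.0681 FPKM. Among pentose phosphate pathway genes, which supply NADPH, 6 of 9 tested members rose and 0 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.00132, and adjusted p = 0.26 with an estimated correlation). The dehydrogenases Pgd and G6pdx rose from 188 ± 4.71 to 333 ± 15.2 FPKM and from 98.8 ± 6.01 to 169.5 ± 8.65 FPKM, and Taldo1 from 147 ± 5.44 to 232 ± 8.74 FPKM. In the iron and ferroptosis list, 8 of 19 tested members rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.0114, and adjusted p = 0.26 with an estimated correlation). Ferritin heavy chain (Fth1) rose from 3711 ± 17.4 to 6511 ± 69.6 FPKM and Sat1 from 34.4 ± 4.57 to 45.4 ± 4.06 FPKM. Without the members that the NRF2 list also holds, glutathione, pentose phosphate and iron lists gave camera adjusted p = 0.0634, 0.0973 and 0.217.

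Oxidant defence genes outside the glutathione system did not pass as a list: 5 of 23 tested members rose and 4 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.252). Srxn1, which repairs peroxiredoxins, rose from 30.1 ± 1.43 to 75.4 ± 4.93 FPKM. Of aryl hydrocarbon receptor and xenobiotic metabolism genes, 5 of 13 tested members rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.0565). This list passed without Vehicle replicate 3 (adjusted p = 0.0443), without SAS replicate 1 (adjusted p = 0.034) and without SAS replicate 2 (adjusted p = 0.0495), and after the GC content and length correction (adjusted p = 0.03). It also passed at a mean of at least 5 FPKM (adjusted p = 0.0272) and with libraries rescaled to a common sum (adjusted p = 0.0395). It did not pass with an estimated correlation (camera adjusted p = 0.322) or without NRF2 list members (camera adjusted p = 0.273). Among metallothioneins and zinc transport genes, 2 of 5 tested members rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.252). Mt2 rose from 467 ± 29.98 to 594 ± 33.5 FPKM.

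Genes of the amino acid response driven by ATF4 were mostly lower. In that list, 6 of 29 tested members rose and 17 fell (6 and 18 adjusted over the list alone, camera adjusted p = 0.0104, and adjusted p = 0.322 with an estimated correlation). Their median log2 fold change was -0.252. Trib3, Aldh18a1 and Chac1 fell, whereas Pycr1 and the transcription factor Atf5, from 43.2 ± 2.33 to 84.3 ± 2.77 FPKM, rose. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation, were also lower: 0 of 20 tested members rose and 10 fell (0 and 10 adjusted over the list alone, camera adjusted p = 0.000974, and adjusted p = 0.419 with an estimated correlation). Cars, the cysteinyl-tRNA synthetase, fell from 46.4 ± 1.27 to 27.9 ± 1.96 FPKM, Nars from 67.1 ± 4.42 to 48.5 ± 2.44 FPKM and Tars from 43.3 ± 1.43 to 31.9 ± 1.69 FPKM. Chaperones of the unfolded protein response were higher: 17 of 22 tested members rose and 1 fell (18 and 1 adjusted over the list alone, camera adjusted p = 5.04e-05, and adjusted p = 0.44 with an estimated correlation). Pdia4, an endoplasmic reticulum disulfide isomerase, rose from 126 ± 4.41 to 210.1 ± 25.9 FPKM, Sdf2l1 from 69.4 ± 1.25 to 99.8 ± 10.7 FPKM and the lectin chaperone Calr from 1005 ± 36.9 to 1381 ± 161 FPKM, while Herpud1 fell from 59.97 ± 3.23 to 44.97 ± 6.25 FPKM. The heat shock response list did not pass: 4 of 17 tested members rose and 5 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.97). Hspa1b rose from 2.79 ± 0.0611 to 5.63 ± 0.69 FPKM and Dnaja1 fell from 36.4 ± 3.17 to 26.3 ± 3.73 FPKM.

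In the transsulfuration and methionine cycle list, 3 of 13 tested members rose and 8 fell (3 and 9 adjusted over the list alone, camera adjusted p = 0.0433, and adjusted p = 0.322 with an estimated correlation). Amd1 and Srm, which make polyamines, fell from 18.3 ± 1.63 to 12.5 ± 1.53 FPKM and from 187 ± 6.9 to 136 ± 6.95 FPKM, and Ahcy, which hydrolyses S-adenosylhomocysteine, from 86.2 ± 3.31 to 62.1 ± 2.32 FPKM. The list's call was lost with quantile normalization (adjusted p = 0.0595) and with a correction for GC content and transcript length (adjusted p = 0.115). It was also lost with a replicate block (adjusted p = 0.0563), without Vehicle replicate 1 (adjusted p = 0.0567) and without SAS replicate 3 (adjusted p = 0.0524).

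Most DNA replication and mitosis genes tested were lower in SAS, by a modest amount. Of the replication list, 0 of 48 tested members rose and 38 fell (0 and 40 adjusted over the list alone, camera adjusted p = 8.26e-14, and adjusted p = 0.26 with an estimated correlation). Their median log2 fold change was -0.352. Mcm7, a subunit of the replicative helicase, fell from 154 ± 7.81 to 103 ± 4.41 FPKM, Gins1 from 24.7 ± 1.15 to 16.4 ± 1.06 FPKM and Uhrf1 from 166 ± 11.1 to 118 ± 8.37 FPKM. In the mitosis list, 0 of 44 tested members rose and 38 fell (0 and 39 adjusted over the list alone, camera adjusted p = 8.26e-14, and adjusted p = 0.273 with an estimated correlation). Their median log2 fold change was -0.354. The spindle motors Kif11 and Kif23 fell from 4.6 ± 0.265 to 2.49 ± 0.010 FPKM and from 12.3 ± 1.74 to 8.13 ± 0.675 FPKM, and cyclin A2 (Ccna2) from 67.6 ± 1.52 to 47.6 ± 1.47 FPKM. In the list named for cyclins, CDKs and inhibitors outside these phases, 2 of 17 tested members rose and 7 fell (2 and 10 adjusted over the list alone, camera adjusted p = 0.0114, and adjusted p = 0.322 with an estimated correlation). It also holds other regulators, such as Mxd4 and E2f8. The inhibitor Cdkn1a rose from 192 ± 13.1 to 288 ± 15.9 FPKM and Mxd4 from 14.6 ± 2.45 to 27.7 ± 2.42 FPKM, while Cdkn1b fell from 23.2 ± 1.12 to 15.98 ± 1.05 FPKM. This list's call was lost among genes with a mean of at least 5 FPKM (adjusted p = 0.102). Of p53 targets, 12 of 26 tested members rose and 3 fell (13 and 3 adjusted over the list alone, camera adjusted p = 0.0114, and adjusted p = 0.322 with an estimated correlation). Plk3 rose from 4.42 ± 0.396 to 8.22 ± 0.477 FPKM and the epoxide hydrolase Ephx1 from 136 ± 10.96 to 229 ± 23.6 FPKM.

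Genes of folate and nucleotide synthesis were also lower: 2 of 31 tested members rose and 16 fell (2 and 17 adjusted over the list alone, camera adjusted p = 0.000127, and adjusted p = 0.322 with an estimated correlation). Mthfd2 fell from 90.1 ± 2.57 to 57.9 ± 2.5 FPKM, thymidylate synthase (Tyms) from 32.9 ± 0.582 to 23.7 ± 1.24 FPKM and the purine enzyme Paics from 72.3 ± 2.35 to 52.7 ± 2.45 FPKM, while Aldh1l2 rose from 3.71 ± 0.141 to 10.1 ± 0.702 FPKM. Among ribosome biogenesis genes, 0 of 31 tested members rose and 14 fell (0 and 14 adjusted over the list alone, camera adjusted p = 0.000344, and adjusted p = 0.473 with an estimated correlation). Nucleophosmin (Npm1) fell from 318 ± 38.7 to 222 ± 36.7 FPKM and fibrillarin (Fbl) from 280.1 ± 12.5 to 221 ± 8.18 FPKM. Ribosomal protein genes had a median log2 fold change of -0.13: 0 of 67 tested members rose and 13 fell (0 and 10 adjusted over the list alone, camera adjusted p = 0.000165, and adjusted p = 0.615 with an estimated correlation). The share of ribosomal protein genes that fell was near that of all genes tested (1963 of 10615). Rpl11 fell from 1324 ± 106 to 1097 ± 52.8 FPKM. By fry, the biogenesis and ribosomal protein lists gave adjusted p = 0.0596 and 0.161. Replication-dependent histones, which have near-identical copies and mostly lack poly(A) tails, did not pass: 2 of 17 tested members rose and 8 fell (2 and 8 adjusted over the list alone, camera adjusted p = 0.0716). Without Vehicle replicate 2 and without SAS replicate 1 the list gave adjusted p = 0.0313 and 0.0136, and with libraries rescaled to a common sum 0.0384. An estimated correlation gave camera adjusted p = 0.419 for the histone list. At a mean of at least 5 FPKM its direction turned upward (adjusted p = 0.805).

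Most pigment cell genes tested rose. In the melanocyte list, 17 of 22 tested members rose and 0 fell (19 and 0 adjusted over the list alone, camera adjusted p = 2.20e-09, and adjusted p = 0.26 with an estimated correlation). Their median log2 fold change was 0.366. The melanocortin receptor Mc1r rose from 48.4 ± 2.49 to 99.03 ± 4.39 FPKM, the channel Trpm1 from 11.1 ± 0.685 to 24.4 ± 0.688 FPKM and the melanosomal receptor Gpr143 from 33.4 ± 2.39 to 59.5 ± 6.69 FPKM. Of lysosome and autophagy genes, 19 of 37 tested members rose and 1 fell (22 and 2 adjusted over the list alone, camera adjusted p = 1.25e-06, and adjusted p = 0.26 with an estimated correlation). The protease cathepsin D (Ctsd) rose from 880.0 ± 65.2 to 1600.0 ± 167 FPKM, the sialidase Neu1 from 18.4 ± 1.62 to 37.97 ± 2.68 FPKM, Optn from 5.91 ± 0.329 to 12.8 ± 0.662 FPKM and Gabarapl1 from 58.8 ± 0.405 to 95.3 ± 1.64 FPKM. The invasive and neural crest list did not pass: 3 of 14 tested members rose and 6 fell (4 and 7 adjusted over the list alone, camera adjusted p = 0.252). Its members Mcam and vimentin (Vim) fell from 163 ± 13.3 to 85.9 ± 7.06 FPKM and from 1028 ± 64.1 to 729.6 ± 8.93 FPKM, while Axl rose from 6.56 ± 0.27 to 10.1 ± 0.663 FPKM. Among extracellular matrix and remodelling genes, 3 of 19 tested members rose and 7 fell (3 and 8 adjusted over the list alone, camera adjusted p = 0.384). The integrin Itgb3 rose from 3.14 ± 0.0971 to 9.47 ± 0.832 FPKM and Timp2 fell from 111 ± 4.29 to 65.2 ± 6.08 FPKM.

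Of TGF-beta and SMAD targets, 8 of 13 tested members rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.00545, and adjusted p = 0.26 with an estimated correlation). The members with the highest log2 fold changes were Id1, Id3 and Id2, genes known as targets of BMP signalling. Id2 rose from 125 ± 9.08 to 213 ± 29.5 FPKM and Tgfb1 from 11.6 ± 0.562 to 20.2 ± 2.0 FPKM. Immediate early genes, induced by growth factor and stress signals, were mostly higher: 16 of 26 tested members rose and 3 fell (17 and 6 adjusted over the list alone, camera adjusted p = 0.0011, and adjusted p = 0.322 with an estimated correlation). Egr1 (NCBI Gene 13653) rose from 0.397 ± 0.0651 to 2.41 ± 0.687 FPKM (log2 fold change 1.27, SE 0.12, limma adjusted p = 2.57e-05), Junb from 8.8 ± 0.429 to 16.8 ± 1.45 FPKM and the phosphatase Dusp4 from 32.2 ± 1.71 to 60.2 ± 6.0 FPKM, while Etv4 fell from 2.42 ± 0.475 FPKM to 0.78 FPKM in each SAS library. Of YAP and WNT targets, 2 of 9 tested members rose and 4 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.252). Ccn1 rose from 22.2 ± 2.77 to 35.4 ± 1.14 FPKM and Ajuba fell from 28.5 ± 0.198 to 19.1 ± 1.71 FPKM.

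In the hypoxia list, 10 of 23 tested members rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 0.00467, and adjusted p = 0.487 with an estimated correlation). Fry gave adjusted p = 0.0689. The prolyl hydroxylase P4ha1 rose from 13.2 ± 0.758 to 22.7 ± 0.356 FPKM and Adm from 1.01 ± 0.107 to 2.0 ± 0.0709 FPKM. In the glycolysis list, 7 of 21 tested members rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.00112, and adjusted p = 0.462 with an estimated correlation). The lactate exporter Slc16a3 rose from 116 ± 25.98 to 215 ± 37.5 FPKM and the glucose transporter Slc2a1, also a hypoxia list member, from 46.4 ± 7.7 to 67.2 ± 10.6 FPKM. Among nuclear genes of oxidative phosphorylation, 1 of 42 tested members rose and 3 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.76). For cholesterol synthesis and uptake, 3 of 25 tested members rose and 3 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.568). Hmgcs1 fell from 10.7 ± 0.427 to 8.11 ± 0.845 FPKM. In the fatty acid synthesis list, 4 of 16 tested members rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.492). Me1, an NADPH-forming enzyme, rose from 24.7 ± 0.509 to 45.03 ± 2.13 FPKM. Of fatty acid oxidation genes and PPAR targets, 6 of 16 tested members rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.0668). The list passed without SAS replicate 3 (adjusted p = 0.0424) and with no filter (adjusted p = 0.0159), but not with an estimated correlation (adjusted p = 0.322). The median and the mean log2 fold change differed in sign for the lists of cystine transport (0.052 and -0.064), heat shock (-0.035 and 0.028), fatty acid synthesis (-0.014 and 0.094) and PD-L1 regulators (-0.029 and 0.057), none of which passed.

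Cd274, which encodes the checkpoint ligand PD-L1, was near the floor at 0.28 ± 0.0346 FPKM in vehicle and 0.643 ± 0.131 FPKM in SAS, below the filter of 0.5 mean FPKM. All 3 SAS values lay above all 3 vehicle values (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give), and limma without the filter gave a log2 fold change of 0.358 (SE 0.058, adjusted p = 0.00664). Irf4, a transcription factor also expressed in pigment cells, was listed at 0.0133 ± 0.00577 FPKM in vehicle and 0.080 ± 0.0436 FPKM in SAS (exact two-sided permutation p = 0.1; adjusted p = 0.0573 without the filter). Among immune checkpoint ligands, 3 of 10 tested members rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.284). Lgals3 and Pvr rose from 40.98 ± 4.08 to 60.6 ± 4.14 FPKM and from 12.4 ± 0.902 to 17.7 ± 3.12 FPKM, while Nectin2 fell from 36.1 ± 1.23 to 27.7 ± 3.9 FPKM. For regulators of PD-L1 transcription, 5 of 21 tested members rose and 4 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.751). Nfkb1 fell from 17.3 ± 0.848 to 11.4 ± 0.774 FPKM, while Egr1 rose, as did Stat3, from 13.2 ± 0.50 to 17.5 ± 0.79 FPKM. In the interferon response list, 6 of 18 tested members rose and 3 fell (6 and 5 adjusted over the list alone, camera adjusted p = 0.669). The chemokine Cxcl10 fell from 29.4 ± 1.32 to 15.8 ± 1.27 FPKM and Ifi27 rose from 21.7 ± 1.41 to 30.4 ± 1.72 FPKM. Of antigen processing and presentation genes, 3 of 11 tested members rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.252). The class I gene H2-D1 rose from 46.2 ± 3.36 to 62.8 ± 8.76 FPKM.

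In the list of NF-kB targets and inflammatory mediators, 1 of 11 tested members rose and 4 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.183). Cxcl1 and the chemokine Ccl5, from 3.25 ± 0.205 to 1.8 ± 0.466 FPKM, fell. Of secreted factors that act on macrophages, 3 of 11 tested members rose and 6 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.252). The growth factor Csf1 fell from 10.5 ± 0.973 to 6.99 ± 0.815 FPKM and Anxa1 from 34.7 ± 4.7 to 18.7 ± 4.81 FPKM, while Tgfb1 rose. For extracellular vesicle biogenesis, 4 of 30 tested members rose and 3 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.596). Rab27a, also a melanocyte list member, rose from 27.3 ± 0.941 to 41.7 ± 1.9 FPKM and Sdc1 fell from 49.8 ± 1.52 to 32.4 ± 3.17 FPKM. Among apoptosis regulators, 7 of 19 tested members rose and 4 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.196). Cflar, an inhibitor of caspase-8 activation, rose from 3.25 ± 0.0794 to 5.58 ± 0.264 FPKM.

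Markers of other cell types were low. Of the macrophage and leukocyte markers, 3 of 3 tested members rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.0104, and adjusted p = 0.26 with an estimated correlation). Cd68 rose from 2.26 ± 0.262 to 3.97 ± 0.0404 FPKM, Fcer1g from 1.53 ± 0.176 to 2.38 ± 0.232 FPKM and Lyz2 from 0.47 ± 0.0173 to 0.86 ± 0.114 FPKM, while Csf1r stood at 0.00333 FPKM or less in group mean. Pdgfrb was the 1 fibroblast and endothelial marker tested, at 2.26 ± 0.288 FPKM in vehicle and 1.77 ± 0.235 FPKM in SAS (adjusted p = 0.054); it passed with a replicate block (adjusted p = 0.019), without Vehicle replicate 1 (adjusted p = 0.029) and without SAS replicate 3 (adjusted p = 0.0329). None of the 6 keratinocyte and epithelial markers in the table reached the filter.

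**Figure D2:**
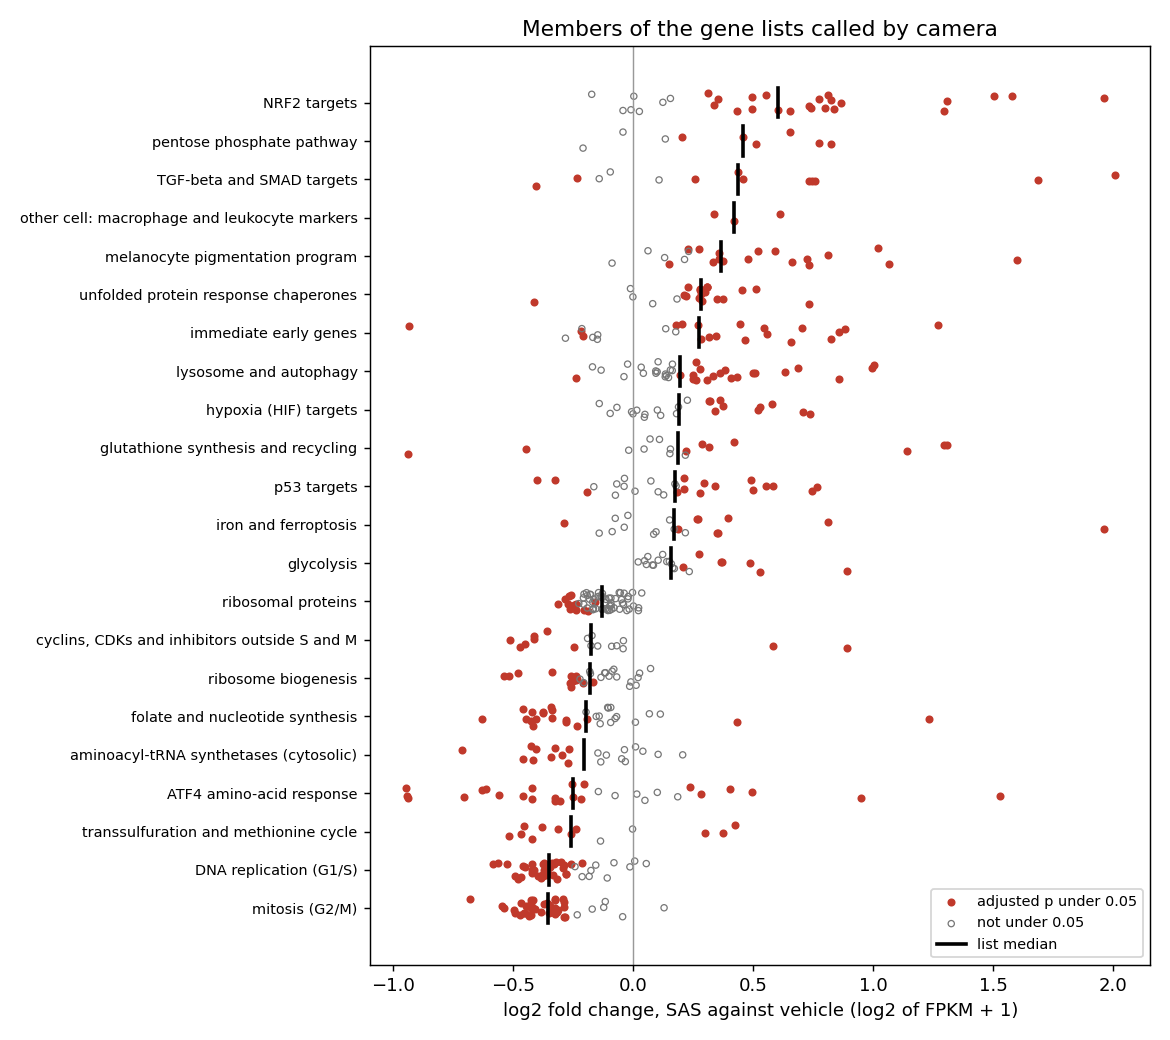
Log2 fold change of SAS against vehicle on the log2(FPKM + 1) scale (horizontal axis) of each tested member of the 22 lists with a camera adjusted p below 0.05, with filled points for members at limma adjusted p below 0.05, open points for the rest and vertical bars at list medians. Medians run from -0.354 for mitosis to 0.604 for NRF2 targets.

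Of the 43 lists tested, 22 passed with camera's preset correlation of 0.01, 13 higher and 9 lower, but with a correlation estimated from the libraries NRF2 targets alone passed. That loss is not due to correlation in every list, since the setting also leaves camera few degrees of freedom. For NRF2 targets the estimate was 0.003, yet the unadjusted camera p went from 5.76e-15 to 0.00107. The iron, pentose phosphate and leukocyte lists had negative estimates (-0.018, -0.022 and -0.016) and still lost their calls. Other lists that lost their calls had high estimates, among them ribosomal proteins (0.636), unfolded protein response chaperones (0.535) and ribosome biogenesis (0.443). For those, the part played by correlation was not separated from that of the degrees of freedom. Splits of the 6 libraries that mix vehicle and SAS passed up to 20 lists with the preset correlation, so the number of lists that passed does not by itself set the treatment apart. Fry passed 7 lists that camera did not: xenobiotic metabolism (adjusted p = 0.00321), fatty acid oxidation (0.00641), NF-kB targets (0.0203), oxidant defence (0.0238), apoptosis regulators (0.0255), metallothioneins (0.0396) and macrophage-acting factors (0.0451).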

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

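The correction for GC content and transcript length and the removal of NRF2 list members from other lists were chosen after the data were seen, as were the tests over other splits of the libraries. The number of changed genes, 3969, ranged from 2787 (mean of at least 5 FPKM, fewer genes tested) to 4779 (array weights), was 2890 to 3762 with 1 library left out and 4475 after the added correction. The 50 genes changed at least 2-fold became 136 with a pseudocount of 0.1, where low genes count for more by construction, and 45 to 56 with 1 library left out. Of the lists, 22 passed; with an estimated inter-gene correlation 1 did (NRF2 targets), with fry 26 and with 1 library left out 21 to 24. After the added correction 22 passed, and 18 without NRF2 list members elsewhere; the transsulfuration list, which holds 0 of them, lost its call through the adjustment alone. Replicate numbers gave no clear pairing: deviations of same-numbered libraries correlated at -0.08, 0.15 and 0.23, and those of differently numbered ones at -0.41 to 0.35. With a replicate block, 4345 genes changed, 51 at least 2-fold, and 21 lists passed. Across settings fixed before the data were examined, 71.4 to 99.6% of the changed genes that were tested kept their call and 0 changed sign. For named genes, 2741 of 2806 values stayed on their side of the threshold, 58 lost a call and 7 gained one. Most named genes were picked for large changes in the same data, so this stability is partly built in. Over the 10 splits of the 6 libraries into 3 and 3, 1 split, the real one, gave as many changed genes (3969, against 1 at most otherwise), 2-fold genes (50, against 1) and lists (22, against 20); 10 splits are too few for a share under 0.05. Each other split still sets 2 libraries of a group against 1, so camera's preset calls respond to part of the difference or to any structure shared by 3 libraries, which was not separated. Unknown depth limits what can be said of genes near 0, such as Cd274 and Irf4.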

Other observations

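The families, and the tests on single libraries, on shared list members and on leukocyte genes, were chosen after their results had been seen at least in part. The tests on GC content and length were set before they were run, with the uncorrected values and the GC trend known. Of 12 gene families defined by symbol, some of whose members stand in the fixed lists, 10 passed with camera's preset correlation and none with an estimated one. Some families that include RNA splicing factors held many lowered members. Of the hnRNP genes, 13 of 20 fell and 0 rose (camera adjusted p = 1.16e-05, and adjusted p = 0.285 with an estimated correlation). So did 7 of 10 SR factors fall (camera adjusted p = 0.000379, and adjusted p = 0.205 with an estimated correlation). Of Snrp and Lsm genes, 10 of 24 fell (camera adjusted p = 0.00027, and adjusted p = 0.205 with an estimated correlation). Hnrnpd and Hnrnpa2b1 had log2 fold changes of -0.69 and -0.55, and Srsf4 and Snrpb of -0.42 and -0.39. High mobility group genes, which encode chromatin proteins, fell in 7 of 10 cases, with Hmgb2 at -0.76 and Hmgb3 at -0.72 (adjusted p = 0.000155; adjusted p = 0.142 with an estimated correlation). Zinc finger protein genes fell in 38 and rose in 13 of 212 cases (camera adjusted p = 0.00315, and adjusted p = 0.463 with an estimated correlation). The share that fell was near that of all genes tested (1963 lower and 2006 higher of 10615), while the share that rose was smaller.

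Glutathione S-transferases rose in 15 of 20 cases and fell in 1 (camera adjusted p = 8.47e-07; adjusted p = 0.142 with an estimated correlation), among them Gsta4 at 0.74 and Gstm1 at 0.60; close copies may share reads, and some members stand in the NRF2 list, which itself gave adjusted p = 0.0462 with an estimated inter-gene correlation, the 1 list to pass. Subunits of the vacuolar ATPase, the proton pump of lysosomes and melanosomes, rose in 10 of 19 cases, led by Atp6v0a1 at 0.65 (adjusted p = 5.38e-05; adjusted p = 0.142 with an estimated correlation). Solute carriers rose in 69 and fell in 23 of 186 cases (adjusted p = 0.000124; adjusted p = 0.499 with an estimated correlation), Tmem genes in 57 and 9 of 150 (adjusted p = 1.42e-05; adjusted p = 0.285 with an estimated correlation) and Dusp phosphatases in 6 and 1 of 18 (adjusted p = 0.0196; adjusted p = 0.285 with an estimated correlation). Proteasome subunits (6 of 36 rose, 0 fell; adjusted p = 0.264) and mitochondrial ribosomal proteins (8 rose and 9 fell of 78; adjusted p = 0.432) did not pass.

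Replication and mitosis genes fell by a median of 0.353 on the log2 scale over 92 members with a GC value. With an estimated correlation neither list passed (adjusted p = 0.26 for replication and adjusted p = 0.273 for mitosis). Fold changes tracked GC content across genes (Spearman 0.187; genes are not independent replicates), from a median of -0.104 in the GC-poorest of 10 equal bins to 0.04 in bin 9. After a correction for GC content and transcript length the members' median was -0.357. Its bootstrap SE of 0.015 came from resampling genes, so it does not measure the spread between libraries. With any 1 library left out the uncorrected median lay between -0.376 and -0.328. So neither that trend nor a single library accounts for the fall. Bin medians from -0.104 to 0.04 had left the correction little room to remove it. What causes the fall was left open. A difference of culture time or cell density, if the 0 h columns mean cells before incubation, is confounded with treatment and was not tested.

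Of 29 tested ATF4 list members, 17 were lower and 6 higher, while 22 of 29 NRF2 targets were higher. With an estimated correlation the ATF4 list did not pass (adjusted p = 0.322). All 17 lowered ATF4 list members were still lower after the GC content and length correction. Without the members that the nucleotide, folate and transsulfuration lists also hold, 14 of 26 were lower, but too few members are shared for that test to decide anything. Fresh against conditioned medium, confounded with treatment under the same reading of the 0 h columns, may shift amino acid genes and was not tested.

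Macrophage and leukocyte markers rose, on 3 tested genes, and 7 of the 15 markers written for this list were in the table. With an estimated correlation this list did not pass (adjusted p = 0.26). If macrophages were among the SAS-treated cells, their other abundant transcripts should rise with Cd68, which gained 1.71 FPKM. Of 9 other leukocyte transcripts looked at, 8 gained less than 0.5 times as much, namely Lyz2 (0.39 FPKM), Cd74 (0.383 FPKM), Itgb2 (0.223 FPKM), Coro1a (0.03 FPKM), Laptm5 (0.0267 FPKM), Csf1r (0.00333 FPKM), Ctss (listed at 0) and Apoe, which was lower in SAS. Lcp1, at 1.27 FPKM, gained more, as did the marker Fcer1g, at 0.857 FPKM, which was not among the 9. A first form of the test had left out Lcp1, Coro1a and Apoe although their values had been seen, and they were put back. Apoe, at 844.6 and 791.8 FPKM, would hide a small share and most others lie near the floor, with 2 of the 9 between 1 and 100 FPKM: Lcp1, which goes with macrophages, and Coro1a, which goes against them. So macrophages among the cells cannot be told apart from expression of Cd68, itself a lysosomal protein, Fcer1g and Lcp1 by the melanoma cells.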
